A study of Mus musculus with 10 samples.

How the data were processed

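TET2 binding was measured by ChIP-seq in mouse embryonic stem (ES) cells. Chromatin was crosslinked with disuccinimidyl glutarate and formaldehyde, per the labels' protocols. Of the 10 samples, 8 immunoprecipitations had a peak list and were analysed, 2 in each of 4 groups. An input library and an IgG library had no list and were not analysed here.

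The submitters' processing notes name Trimmomatic, Bowtie2, MACS2, DiffBind, DESeq2 and the mm10 build, with no versions, roles or order. Peaks had been called separately in each library by the authors, since each deposited list carries the peaks of 1 library. The deposited peak names carry the words q10, rmChrM, rmDUP and IgG. For each peak the deposited lists give a position, a score, a fold enrichment at the summit over the control track (a linear ratio), the −log10 p and −log10 q values and the summit offset. The score in the deposited lists is the −log10 q value scaled up and cut to a whole number. The score, fold and −log10 values are the authors' own, and were used only to describe, rank or filter peaks within a list. The lowest −log10 q of any list was 2.01, in FLAG-TET2 replicate 1. Neither read counts nor read depth were given in the sources used here, so the number of peaks in a list mixes binding with an unknown depth, and site calling on reads, as DiffBind does, was not possible.

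Peaks on the 21 assembled chromosomes were kept, which left out between 2 and 34 peaks of a list. All peaks of the 8 lists were merged where they shared at least 1 bp, which gave 79350 regions with a median width of 243 bp. A region was present in a library if it held at least 1 of its peaks. Anti-TET2 specific regions had a peak in both wild-type lists and in neither knockout list. Anti-FLAG specific regions had a peak in both FLAG-TET2 lists and in neither parental list. Common TET2 regions had a peak in all 4 of these target lists and in none of the 4 control lists, and control regions had a peak in at least 2 of the 4 control lists. The groups, region classes, gene lists, tests and most of the other settings tried were fixed before the data were examined.

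Peak numbers were compared on a log2 scale with a two-sided exact permutation test, with labels permuted within each antibody over 36 arrangements. A comparison of 2 against 2 libraries cannot give a p below 0.333. The overlap of the anti-TET2 and anti-FLAG specific regions was set against 1000 random placements of the former on their own chromosomes, and against the number expected of independent sets within the 79350 regions. Shares of regions were compared with two-sided Fisher's exact tests, in which regions are units and not replicates, so those p-values describe these lists. Odds ratios are given with 95% confidence intervals. Several Fisher p-values fell below the smallest number that double precision holds, and for those the odds ratio and its interval are given alone.

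Gene positions came from a table of 21887 protein-coding genes of GRCm38.p6, the assembly that mm10 represents. The table gives neither strand, exons nor transcription start sites, and no genome sequence was used here. The planned promoter share, CpG density and motif tests were therefore not run. In place of the promoter share, the share of regions within 1 kb of either end of a gene span was computed, a choice made after the gene table was seen. Each region was given to the protein-coding gene whose span was nearest, within 50 kb, in place of the planned distance to the start site. For each of 10 gene lists, the share of tested genes that were nearest gene of at least 1 common region was compared with all other genes that were nearest gene of any of the 79350 regions, by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 10 lists. Of the 205 symbols in the lists, 201 matched the gene table. After the result was seen, the lists were also set against 10000 random gene lists matched on gene length, on the number of merged regions or on the number of regions with a control peak.

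Named regions were chosen by rule. They were the 10 common regions with the highest mean within-list percentile of −log10 q over the 4 target lists, and by the same percentile up to 4 members of each gene list nearest a common region. The rule also took the 5 leading regions of each reagent that were absent from both lists of the other, the 5 leading regions present in all 8 lists, and the Tet2 gene in every list. Further list members (Esrrb, Tbx3, Dppa3, Pou5f1, Sall4, Spry4, Dnmt3b and Cdx2) and the genes named for holding several common regions were chosen after their values were seen. Some regions and genes that the rule takes are not reported here. Percentiles rank peaks within a list and were never compared between lists as signal.

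Alternatives were a stricter threshold (−log10 q of at least 5), 200 bp summit windows in place of whole peaks, lists shortened to the 2259 leading peaks of each, filtering by the same-numbered control (a replicate block), other distances and backgrounds, and leaving out each library in turn. The code was tested on simulated peak lists with the real lists' lengths. Of 200 regions placed in the 4 target lists, 197 were recovered, and 0 others were called. The simulated background peaks were placed at random and independently in each list, whereas 253 real regions had a peak in all 8 lists. The 0 therefore does not measure false calls in the real lists. Of 500 random gene lists of 20 genes, 2.6% gave an unadjusted p under 0.05 in Fisher's exact test. All of 200 lists built with 12 of 20 genes bound did so. Those lists have the same counts by construction, so they are a single outcome and not a rate of detection. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.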

Results

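TET2, a dioxygenase that oxidises methylated cytosine in DNA, was mapped by ChIP-seq in mouse ES cells grown in serum with LIF and inhibitors of GSK-3 and MEK. An antibody against the N-terminal part of TET2 was used on wild-type cells, whose Tet2 alleles are floxed, and on Tet2 knockout cells. An anti-FLAG resin was used on cells whose own TET2 carries a FLAG tag and on the untagged parental cells. Each of the 4 groups had 2 libraries, and each library had its own list of peaks. Wild-type and FLAG-TET2 libraries are called target lists here, and knockout and parental libraries, which lack the epitope, control lists. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. Only the tests of peak number measure that spread. The other p-values take regions or genes as units and measure no spread between samples. The sequencing depth behind each list is unknown.

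In both arms the mean number of TET2 or FLAG peaks was higher in cells with the epitope than in cells without it, but the replicates of each group differed widely. The wild-type lists held 38546 and 18826 peaks, and the knockout lists 2261 and 11702. The FLAG-TET2 lists held 63612 and 28258 peaks, and the parental lists 36549 and 10132. On the log2 scale, target lists exceeded control lists by 1.76 (3.40-fold in the geometric mean). The difference was 5.24-fold with the TET2 antibody and 2.20-fold with the FLAG resin. In all 4 same-numbered pairs of a target and its control list the target list was longer (log2 differences of 4.09, 0.686, 0.799 and 1.48). The two-sided exact permutation test gave p = 0.111 (n = 4 and 4 libraries), but the smallest p it can give is 0.0556, so it cannot show a difference larger than the spread between replicates. The same holds for the difference between the arms (exact permutation p = 0.611). Without knockout replicate 1 the log2 difference over both arms was 1.17, and without parental replicate 1 it was 2.23. The fold of each arm therefore depended on single lists. The parental replicate 1 list held nearly as many peaks as the wild-type replicate 1 list.

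**Figure D1:**
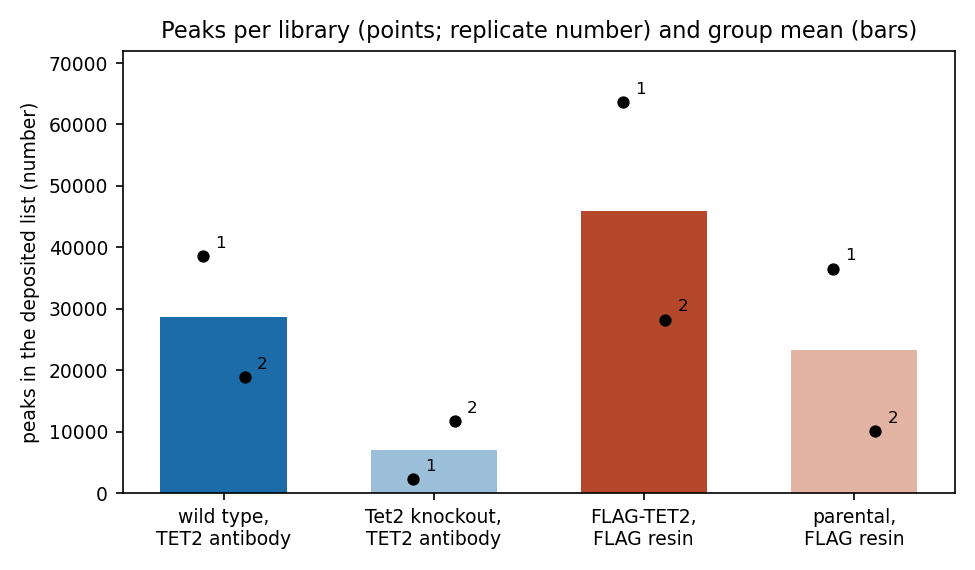
Number of peaks in each deposited list (points, with the replicate number) and mean of the 2 lists of each group (bars). The wild-type lists, with 38546 and 18826 peaks, lie above the knockout lists, with 2261 and 11702, while parental replicate 1 (36549) lies above FLAG-TET2 replicate 2 (28258).

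The Tet2 gene itself (chromosome 3, 133463677 to 133545136, mm10) carried peaks in both wild-type lists and both FLAG-TET2 lists. Wild-type replicates 1 and 2 held 8 and 4 peaks over the gene span, and FLAG-TET2 replicates 1 and 2 held 13 and 10. Knockout replicates 1 and 2 held 0 and 1 peaks, and parental replicates 1 and 2 held 7 and 0. The merged regions over the gene numbered 14, and 1 of them, at 133518184 to 133519187 inside the gene span, had a peak in the 4 target lists and in no control list. A region at 133543511 to 133545212, across the end of the gene span, had peaks in the 4 target lists and also in parental replicate 1. The number of peaks over the gene was not tested, and it does not check the deletion, since it measures binding and not the gene's presence.

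Many of the regions found with the TET2 antibody were also found with the FLAG resin on tagged TET2. The leading common regions lay in or near Gabbr2, which encodes a GABA receptor subunit, Chn2, Max, the partner of MYC, Magi1 and Zyg11a. The region in the span of Gabbr2 (chromosome 4, 46665266 to 46665942) had authors' fold enrichments of 35.4 and 20.6 in wild-type and 35.6 and 23.2 in FLAG-TET2 replicates 1 and 2. The region in the span of Chn2 (chromosome 6, 54096843 to 54097420) had folds of 27.8 and 16.2 in wild-type and 38.8 and 25.0 in FLAG-TET2 replicates. The region near Max (chromosome 12, 76965067 to 76965469) lay 2.74 kb outside the gene, with folds between 19.8 and 35.4. Others of the 10 lay near Lama5, a laminin chain, Cacna1a, a calcium channel subunit, Msmb and Wnt10a, a WNT ligand. Over the 10 regions the authors' folds in the target lists ran from 11.4, near Wnt10a, to 38.8, in Chn2, and by definition no such region had a control peak.

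The wild-type arm gave 11081 anti-TET2 specific regions and the tagged arm 9846 anti-FLAG specific regions. Of these, 4521 were common TET2 regions, 40.8% of the former and 45.9% of the latter. Each specific set was filtered by the controls of its own reagent alone. A parental peak lay in 39.3% of the anti-TET2 specific regions, and a knockout peak in 10.2% of the anti-FLAG specific regions. Random placement on the chromosomes gave a mean overlap of 47.4 and at most 67 (ratio 95.4, permutation p = 0.001, the smallest that 1000 placements can give), and without FLAG-TET2 replicate 2 the ratio was 42.5. Uniform placement ignores where peaks of any kind lie, so this ratio alone does not show shared TET2 binding. Between knockout and parental lists, which lack the epitope, 6.99% to 32.6% of the shorter list overlapped the longer. That overlap was not set against random placement. Within the 79350 merged regions, independent sets would share 1375, and the observed overlap was 3.29 times that (Fisher's exact test, odds ratio 8.15, 95% interval 7.77 to 8.54). The merged regions include those seen in a single list, such as 17022 in FLAG-TET2 replicate 1 alone, which can enter neither set. Such regions lower the number expected, so this ratio alone does not show shared TET2 binding either. Within the target groups, 97.0% of the shorter wild-type list and 97.4% of the shorter FLAG-TET2 list overlapped the longer list of the same group, against 99.8% for the knockout and 98.4% for the parental lists. The lists were of unequal length, and a smaller share of the merged regions in either list of a group was in both. That share was 46.5% for wild type, 39.4% for FLAG-TET2, 19.4% for knockout and 27.5% for parental lists. The counts of specific and common regions depended on single lists, although leaving out a list removes a condition and can only keep or raise them. Without wild-type replicate 2 the common regions numbered 7482 and the anti-TET2 specific regions 27571, and without FLAG-TET2 replicate 2 or parental replicate 1 the anti-FLAG specific regions numbered 35908 or 16345. With the 2259 leading peaks of each list, 1238 anti-TET2 specific, 254 anti-FLAG specific and 210 common regions were left, and with the knockout lists as the only controls, a choice made after seeing the data, there were 8375 common regions.

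**Figure D2:**
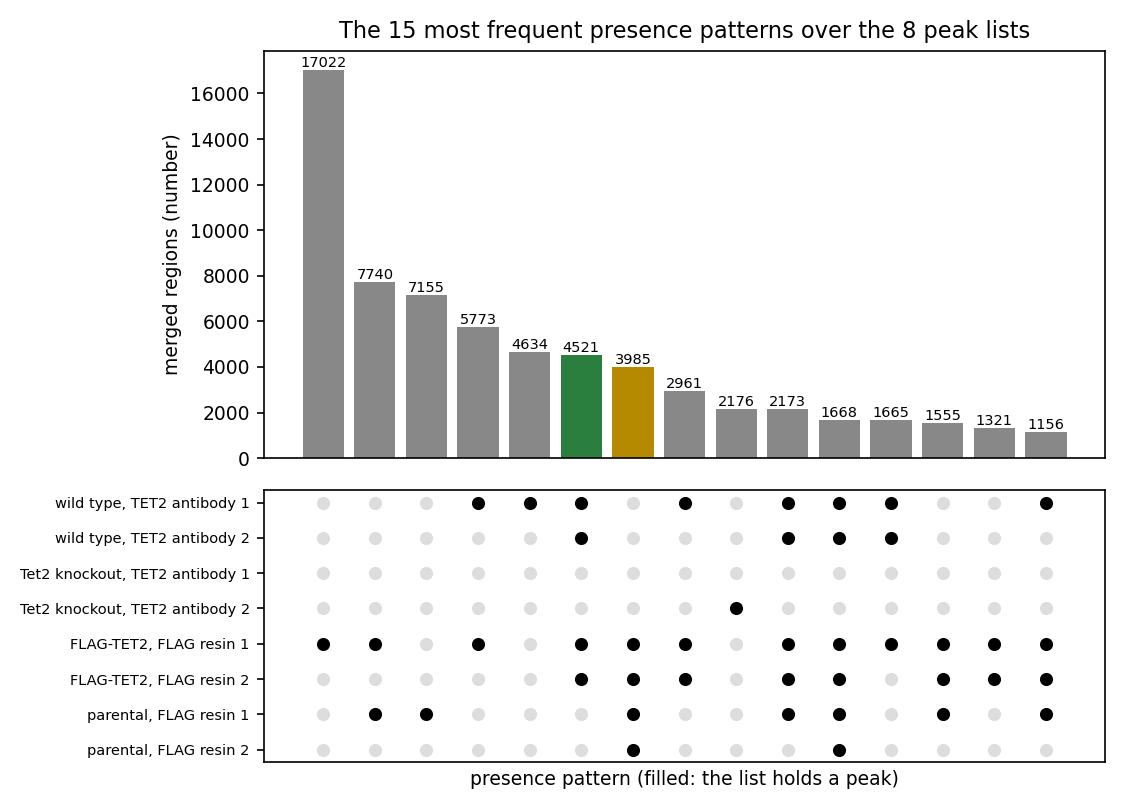
Number of merged regions (bars) for each of the leading presence patterns over the 8 lists, with a filled point where a list holds a peak. The common TET2 regions (green bar, 4521) are followed by the regions present in the FLAG-TET2 and parental lists and in no TET2-antibody list (yellow bar, 3985).

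Some regions were seen with a single reagent. In both wild-type lists but in neither knockout nor FLAG-TET2 list, the leading regions lay in the spans of Ncoa7 and Plekha6, at Cbx8, a Polycomb gene, and 236 kb from Psmd7 and 368 kb from Gm4868. The Cbx8 region (chromosome 11, 119040562 to 119041346) lay at an end of the gene, with authors' folds of 13.9 and 9.88. In both FLAG-TET2 lists but in neither parental nor wild-type list, they lay near Olfr1338, an olfactory receptor gene, in the spans of Morc3 and Gclc, and near Myl1 and Gtdc1. Regions of the former kind numbered 522 and of the latter 1330. Peaks in all 8 lists, where TET2 and its tag were not needed, were found in 253 regions, with those in the spans of Cbln4, Celf6 and Scg3 and 14.6 kb from Frmd5 among the leading ones. The Celf6 region (chromosome 9, 59577920 to 59578652) had authors' folds of 67.1 and 42.8 in FLAG-TET2 and 63.2 and 42.6 in parental replicates 1 and 2.

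Common TET2 regions, which have no control peak by definition, lay at the ends of protein-coding genes less often than control regions did, and the share depended on that filter. Of the 4521 common regions, 453 (10.0%) were within 1 kb of an end of a protein-coding gene, among them the region 0.767 kb from Zyg11a (chromosome 4, 108218855 to 108219501). Of the 12940 control regions, 5849 (45.2%) were, a share 35.2 percentage points higher (Fisher's exact test, odds ratio of common against control regions 0.135, 95% interval 0.122 to 0.150). Common regions placed at random lay at a gene end in 3.85% of cases. The gene span held 52.3% of the common regions and 70.3% of the control regions. Without the filter, the 11942 regions in all 4 target lists were at a gene end in 42.7%. The 3985 regions in both FLAG-TET2 and both parental lists and in no TET2-antibody list, which need no FLAG tag, were there in 11.5%. Anti-TET2 specific regions were at a gene end in 33.9% and anti-FLAG specific regions in 11.2%. Because strand is not known here, a gene end may be a promoter or the far end of a gene.

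Genes of the pluripotent states were found near common TET2 regions more often than other genes. Of 23 genes of the naive state and of 2i/LIF targets, 15 (65.2%, exact 95% interval 42.7 to 83.6%) were nearest gene of a common region within 50 kb, against 17.3% of other genes. They included Klf2 and Tfcp2l1, naive-state transcription factors, Lifr, the LIF receptor, Socs3, a feedback inhibitor of LIF signalling, and Esrrb, Tbx3 and Dppa3. Of 22 core pluripotency genes 13 (59.1%) were, among them Pou5f1, Sox2, Prdm14, Mycn, Sall4 and Jarid2, a Polycomb cofactor. Of 19 genes of the formative and primed state 10 (52.6%) were, among them Otx2, Lef1, the de novo DNA methyltransferases Dnmt3a and Dnmt3b, and the FGF signalling inhibitors Spry2 and Spry4.

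In Fisher's exact tests adjusted over the 10 lists, the odds ratio was 8.94 for the naive list (95% interval 3.55 to 24.4, adjusted p = 4.7e-06), 6.88 for core pluripotency (2.72 to 18.3, adjusted p = 6.8e-05) and 5.29 for the formative list (1.93 to 14.7, adjusted p = 0.0017). Leaving out each library in turn gave odds ratios of 8.25 to 13.8 for naive, 4.92 to 9.90 for core and 3.99 to 7.38 for formative genes. The Sox2 region (chromosome 3, 34668172 to 34668852) lay 15.7 kb from the gene, with authors' folds of 14.5 and 13.6 in wild-type and 23.6 and 11.7 in FLAG-TET2 replicates 1 and 2. The Klf2 region (chromosome 8, 72316041 to 72316689) lay 2.37 kb from the gene, with folds of 17.9 and 13.3 in wild-type and 20.5 and 12.8 in FLAG-TET2. The Otx2 region (chromosome 14, 48654361 to 48655693) lay 1.09 kb from the gene and the Dnmt3a region (chromosome 12, 3889714 to 3890331) inside the gene span, with folds between 8.19 and 14.5 and between 10.6 and 20.1. Near control regions, the same lists gave odds ratios of 1.83 for naive, 3.32 for core pluripotency and 1.67 for formative genes, with adjusted p of 0.30, 0.085 and 0.45 in Fisher's exact tests. Genes of these lists also held many merged regions of any kind. Against 10000 random lists matched on that number, chosen after the result was seen, 0 of the 10 lists passed a permutation test with or without adjustment (naive 15 genes against a mean of 12.5, p = 0.16, adjusted p = 0.55). Within 10 kb of the gene the naive list passed alone, and the core and formative lists had adjusted p of 0.059 each in the exact test.

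The other 7 lists did not pass the test. Of 18 genes of the DNA methylation machinery, 6 were near a common region (33.3%, odds ratio 2.38, adjusted p = 0.27 in Fisher's exact test). These were Tet1, Tet2, Tet3, Smug1, and Dnmt3a and Dnmt3b, which the formative list also holds. The Tet3 region (chromosome 6, 83421740 to 83422124) lay inside the gene span with authors' folds between 8.79 and 24.4, and the Tet1 region (chromosome 10, 62895486 to 62896089) 8.02 kb outside the gene with folds of at least 6.91. Without parental replicate 1 the DNA methylation list passed (odds ratio 3.63, adjusted p = 0.028 in the exact test). Of 23 lineage transcription factors 5 were near a common region, among them Cdx2, Hoxb1, Neurog1 and Sox9. Hematopoietic genes gave 3 of 17, namely Gfi1b, Kit and Hhex, and imprinted genes 3 of 15, namely Grb10, Plagl1 and Usp29. Germline genes gave 2 of 18, Stk31 and Dpep3. Housekeeping genes gave 3 of 20, among them Actb and Eef1a1. Fibroblast genes, which would mark feeder cells, gave 4 of 14, namely Col3a1, Fn1, Vim and Loxl1. Their adjusted p-values lay between 0.57 and 1 in the same exact test. Between 0 and 8 genes of a list were near regions of 1 specific set and not the other, too few for a difference between the reagents to pass an exact McNemar test adjusted over the 10 lists (smallest possible unadjusted p 0.0078).

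**Figure D3:**
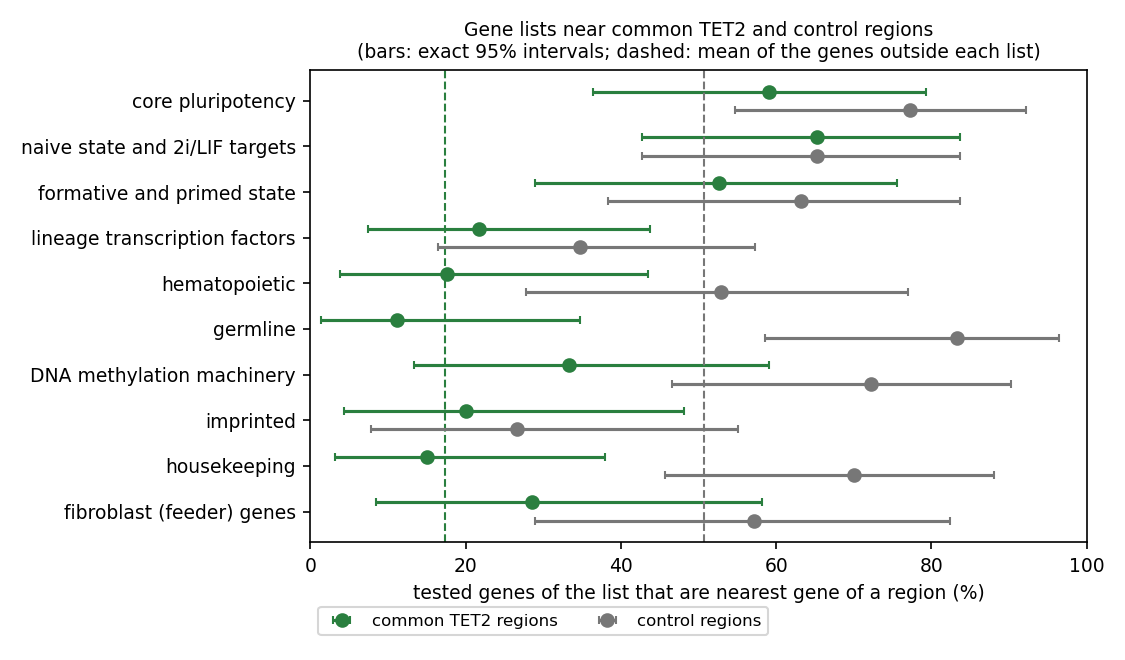
Share of the tested genes of each list that were nearest gene of a common TET2 region (green) or a control region (grey), in percent with exact 95% intervals, and the mean share of genes outside each list (dashed lines). The naive (65.2%), core pluripotency (59.1%) and formative (52.6%) lists lie above the 17.3% of other genes for common TET2 regions.

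**Figure D4:**
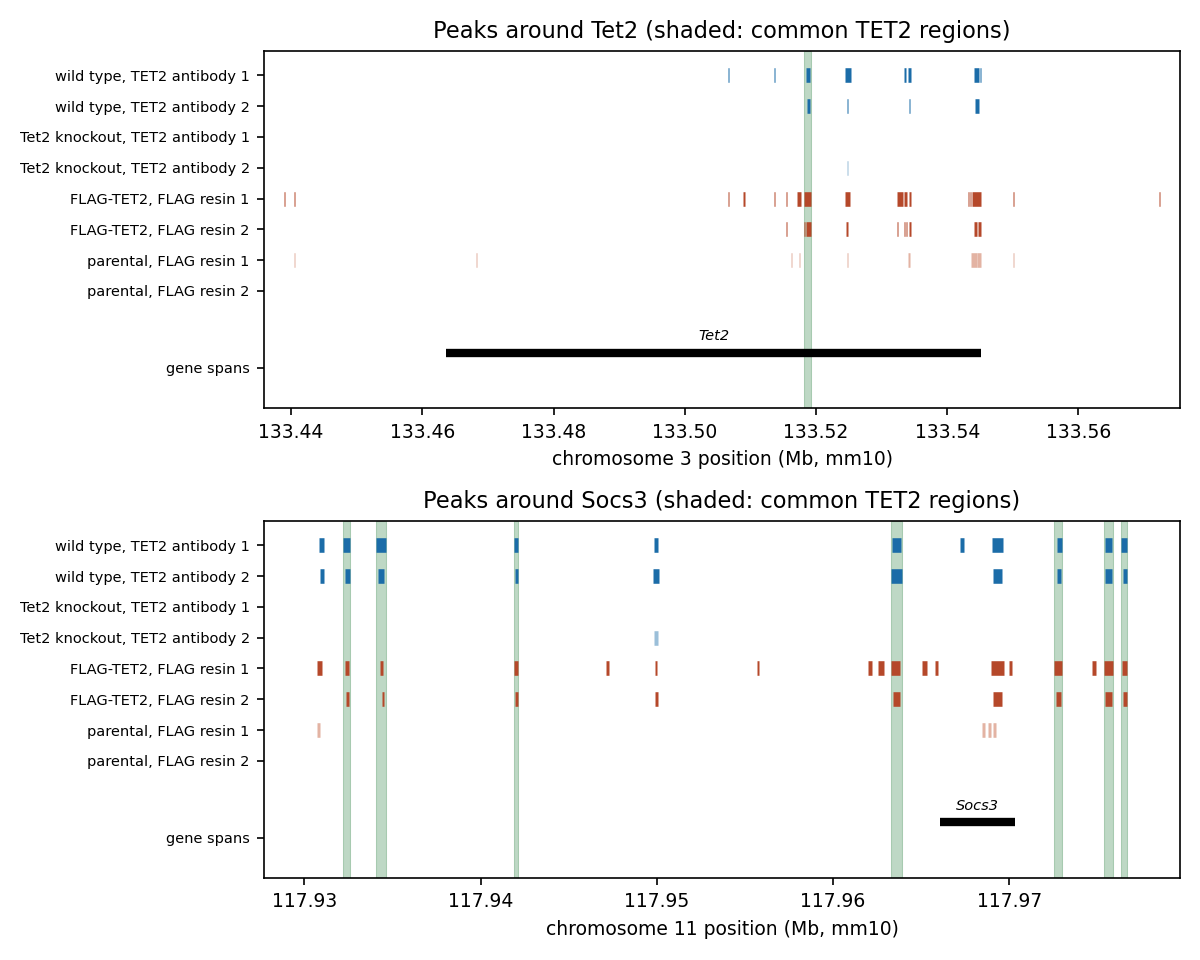
Peaks of the 8 lists around Tet2 and Socs3, by position in Mb, with gene spans in black and common TET2 regions shaded. Tet2 holds 1 common region, and 7 common regions surround Socs3, a gene spanning 4.26 kb, which was chosen for the map after its regions were counted.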

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

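The use of gene ends in place of promoters was chosen after the gene table was seen, and the comparison of regions with no peak at all in the other target lists and the values without each library after the gap was seen. Of the regions in both FLAG-TET2 lists, 59.6% had a peak in at least 1 parental list, while of those in both wild-type lists 34.8% had a peak in at least 1 knockout list. The difference of 24.8 percentage points had an odds ratio of 2.76 (95% interval 2.65 to 2.88, Fisher's exact test over regions), and it rests on parental replicate 1. Without that list the share in FLAG-TET2 was 33.0% and the difference -1.88 points (odds ratio 0.920, 95% interval 0.882 to 0.959), and without FLAG-TET2 replicate 2 it was 6.61 and without knockout replicate 2 49.4 points, so no difference in background between the reagents is reported.

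The share at gene ends differed between the 2 specific sets outside their overlap. Regions that were anti-TET2 specific but not anti-FLAG specific were at a gene end in 50.4% (3303 of 6560), and those that were anti-FLAG specific but not anti-TET2 specific in 12.3% (654 of 5325). The difference was 38.1 percentage points (odds ratio 7.24, 95% interval 6.58 to 7.98, Fisher's exact test over regions), but most of these regions hold some peak of the other reagent, and it was 18.7 points without parental replicate 1 and 20.2 without wild-type replicate 2. For the 522 and 1330 regions with no peak in any target list of the other reagent, the shares were 24.5% and 11.8%, a gap of 12.7 points (odds ratio 2.43, 95% interval 1.85 to 3.17). Background at gene ends that the short knockout lists do not remove is a candidate explanation. Anti-TET2 specific regions at gene ends had a parental peak in 75.6% and the others in 20.7%, an odds ratio of 11.9 (95% interval 10.8 to 13.1), which this explanation needs. Without parental replicate 1 the shares were 35.2% and 5.56% (odds ratio 9.24). These regions include the 4521 common ones, which by definition have no parental peak and lay at a gene end in 10.0%. The odds ratio therefore partly restates the gap and cannot decide the question. Without any control filter, 8.82 percentage points of the 22.7 between all anti-TET2 and all anti-FLAG specific regions were left (41.6% against 32.8%). The filters thus made part of that gap. A region with a parental peak can be anti-TET2 specific but not anti-FLAG specific. Whether the control filters alone make the gap stays open. So does a difference between untagged and tagged TET2, which goes with the reagent and was not tested.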

How the results depend on the processing

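Gene-end shares, other control sets, random lists matched on any measure, gaps between the reagents and the replicate block for gene lists were chosen after seeing the data. The difference in peak number kept its direction in all 11 alternatives (log2 1.17 to 2.36, exact permutation p 0.0556 to 0.28), with 1.76 and p = 0.125, the smallest that 4 pairs can give, under a replicate block; none of these tests can reach 0.05. The overlap ratio stayed above 1 in 11 alternatives (3.29 within the merged regions, and by placement 42.5, without FLAG-TET2 replicate 2, to 110), and common regions were at gene ends less often than control regions in 11 (differences from -52.4 to -29.6 points), as were anti-TET2 specific (-6.49) and anti-FLAG specific regions (-34.1). Across merged regions, the deviations of same-numbered lists had r = -0.012 in the TET2-antibody arm and -0.069 in the FLAG arm. Every merged region holds at least 1 peak, which bears on r, so these values cannot exclude a shared deviation. In the FLAG arm replicate 1 was the longer list in both groups, and 7740 regions had a peak in those 2 lists alone. Under the replicate block there were 11801 anti-TET2 specific, 10201 anti-FLAG specific and 4770 common regions. It called 3 gene lists, so no call changed. Counts moved with the lists used. The leading peaks of each list gave 1238, 254 and 210 regions. Each such region needs a peak in lists cut to 2259 peaks, so no count could exceed 2259. The fall in these counts was therefore forced by the shortening. The knockout lists as the only controls gave 8375 common regions, a number that fewer controls can only raise. Leaving out each library in turn gave 11082 to 27571 anti-TET2 specific, 9880 to 35908 anti-FLAG specific and 4521 to 7482 common regions. The highest were those without replicate 2 of the wild type, of FLAG-TET2 and of the wild type. Without parental replicate 1 there were 16345 anti-FLAG specific regions. A list left out removes a condition, so these counts too could only stay or rise. Gene lists called numbered 4 with anti-TET2 specific regions, where germline genes were depleted, 1 within 10 kb, 0 when matched on merged regions by genes or by common regions, and 3 to 4 without each library, 4 being without parental replicate 1. The gap in control peaks between the reagents, at 24.8 points, went from -1.88 (without parental replicate 1) to 49.4 (without knockout replicate 2), so it turned, and the gene-end gap from 18.7 (without parental replicate 1) to 46.1. Within 10 kb the odds ratios were 3.19 for core pluripotency and 3.25 for the formative list; the cause was not tested. The promoter, CpG and motif alternatives were not run. Depth is unknown, which limits every count of peaks.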

Other observations

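The count of regions per gene, the count of other splits, the matched random lists and the set of control regions as a test of background were chosen after the results they bear on were seen. Some genes had several common regions, and whether this exceeds chance was not tested. Of 2916 genes that were nearest gene of a common region, 695 had at least 2 and 29 at least 5. Socs3, with a span of 4.26 kb, had 7, as many as Myo10 and Pakap, whose spans are 191 and 463 kb, and Etl4, with a span of 900 kb, had 8. Esrrb and Jarid2, a naive-state factor and a Polycomb cofactor, had 5 each, and Ngfr, a neurotrophin receptor gene of 18.9 kb, had 6. The genes named here also held between 13 (Ngfr) and 57 (Etl4) merged regions of any kind, with 21 at Socs3.

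Of 18 germline genes tested, 15 (83.3%) were nearest gene of a control region, against 50.6% of other genes, which did not pass the adjusted test (Fisher's exact test, odds ratio 4.88, adjusted p = 0.076). For anti-TET2 specific regions 2 of 18 were, against 39.2% of other genes (odds ratio 0.194, adjusted p = 0.040), and for anti-FLAG specific regions 2 of 18 against 30.9% (odds ratio 0.279, adjusted p = 0.19). Near common regions the odds ratio was 0.593 (adjusted p = 0.94 in the same exact test), and 0.194 to 0.723 over its 14 alternatives. The 2 specific sets were themselves among those alternatives and were not varied further. These genes had 30 merged regions in all, and the 2 specific sets were not compared with matched lists. The 253 regions present in all 8 lists lay at a gene end in 80.6%. The 3985 regions with a peak in the FLAG-TET2 and parental lists and in no TET2-antibody list lay at a gene end in 11.5%, close to the 10.0% of the common regions, and no gene list passed the test near them (smallest adjusted p = 0.84 and unadjusted p = 0.34 in Fisher's exact tests). The weak peaks of the longer list often had no counterpart in the shorter one. Among regions of wild-type replicate 1, the share with a peak in replicate 2 was 10.2% in the fifth with the lowest −log10 q and 94.7% in the fifth with the highest. The other way, 92.9% of the weakest regions, taken in the same way, of wild-type replicate 2 and 92.7% of those of FLAG-TET2 replicate 2 had a peak in replicate 1.

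Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many regions as the 4521 common ones. The highest other split, with 3985, was that by reagent. Replicate lists overlap, so the 32 splits that part replicates, which gave at most 1156, are no fair comparison, and the 3 that keep them together are too few for a share under 0.05.

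Common regions near naive-state genes were weighed against technical explanations, and long genes were argued against, as the 15 genes were 3.84 times the mean of 10000 lists matched on gene length (permutation p = 0.0001, the smallest they can give). Gene length here is the span alone, so wide flanks within 50 kb of a gene were not tested. Background of the kind seen in the control lists was argued against by lists matched on regions with a control peak. The 15 genes were 2.04 times their mean (permutation p = 0.00060). The odds ratio for control regions was 1.83 (0.727 to 4.98), an interval that overlaps the 3.55 to 24.4 of common regions. In each arm the control lists held fewer peaks on average. Background that gives a peak only in the target lists was therefore not covered. Genes with more peaks of any kind remain a possible explanation, since matching on merged regions left a ratio of 1.20 (15 genes against a median of 13 and an upper bound of 17 for nearly all such lists, permutation p = 0.16), where the unmatched ratio of shares was 3.76. The matched genes often had a common region themselves (a mean of 12.5 genes), which the explanation by more peaks predicts. The merged regions include the TET2 peaks, so this matching may also remove part of a TET2 effect, which was not tested. Counting common regions in the same matched lists, 36 regions were 1.51 times the mean (permutation p = 0.011, adjusted p = 0.11), with 1.55 for the formative (adjusted p = 0.20) and 1.38 for the core list (adjusted p = 0.26), so this explanation stays open and no biological one was tested.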
